A study of Homo sapiens with 3 samples.

How the data were processed

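Total RNA from undifferentiated HUES9 human embryonic stem cells (hESCs) and from cortical neurons derived from them was labelled as biotinylated complementary RNA and hybridised to Illumina BeadArrays, per the labels' protocols. The submitters' processing notes name the R package lumi, with no version; the array version and scanner settings are not given in the sources used here. The deposited array table held the mean bead intensity of each probe on each array, neither background-subtracted nor normalized per the file headers. It also held a detection p-value per probe and array, which the authors deposited beside each intensity, with the number of beads and their standard error. That table covered 9124 probes on 9 arrays, 3 arrays for each of 3 groups. A second deposited table held 1 intensity per gene symbol and group for 31401 symbols. For the 5957 symbols that could be compared with the array table, it was the arithmetic mean of the unnormalized intensities over the probes of a symbol and the 3 arrays of a group.

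The array table named probes but not genes. Every one of its 9124 probes fell in a run of neighbouring probes whose mean equalled a row of the second table in all 3 groups within a relative tolerance of 1e-05. This assigned the probes to 5957 symbols, all between A and E in the alphabet, of which 3963 had 1 probe and 1994 had several. Of these symbols 4238 were current in the reference gene table (GRCh38.p14), 1562 were older names of current genes and 157 were not matched, and the names of the files were kept. Symbols of the 36 spike-in controls were left out after normalization. Genes outside that part of the alphabet had no replicate values here, nor did late symbols in E such as ETS1 and EVX1. For the next 2818 symbols, up to HPRT1, the authors' group means are given with no error. The 22626 symbols after HPRT1 were not used, because their names did not match their values, so that no value is reported for MAPT, POU5F1, NANOG, TUBB3 or MAP2.

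Intensities were background-corrected with limma 3.58.1 (nec with detection p-values, offset 16), log2-transformed and quantile-normalized over the 9 arrays in R 4.3.3. A probe counted as detected in a group when its detection p lay under 0.01 on all 3 arrays. A gene was represented by its brightest probe among those detected in at least 1 group, which left 3439 genes. The fit used limma (lmFit, then eBayes with a trend) over all 3 groups, with Benjamini-Hochberg adjustment over the 3439 genes. A gene was called higher or lower at an adjusted p under 0.05 if it was detected on all arrays of the brighter group. The design fixed beforehand had assumed 1 column per group and a threshold of size, with this limma test in its place should replicate columns be present; they were, so the test was used. Where a gene was undetected on all arrays of the dimmer group, the fold is a lower bound against the lowest detected signal there and is written as at least N-fold. The groups were taken from the labels. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. No slide or scan date was given, and slide effects were not tested.

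The named genes followed a rule fixed beforehand. They were the 10 highest and 10 lowest called genes per comparison with a proper gene symbol, detected on both sides and moving the same way in the authors' group means, and up to 4 genes per direction with the largest bound. BMI1, CDKN2A, APP, GSK3B and DCX were given at any value, as were the 2 highest and 2 lowest measured members of each gene list described. The rule's size limit of 2-fold was replaced by the call, and genes outside the rule are marked as chosen after their values were seen. Results for some genes and lists that the rule selects are not reported here.

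The gene lists, 54 in number, were fixed before the data were examined. In each comparison 36 lists had at least 3 measured members, though not all of them were the same lists. A list stood apart when the median log2 difference of its measured members lay at or below percentile 1, or at or above percentile 99, of 10000 random lists matched on mean signal in 10 bins. Competitive tests of the same lists with limma's camera, with a preset and with an estimated correlation between genes, were added after the data had been seen. With the preset correlation 6 lists of the knockdown comparison and 12 of neurons against hESCs had an adjusted p under 0.05. With the estimated correlation 1 and 0 did, and the adjusted p given for a list below is from that test. Members without replicate values could not enter a list.

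The procedure was tested on simulated arrays with known changes. For the knockdown comparison, over 3400 genes, it recovered 12 of 50 genes changed 1.25-fold, 32 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 3-fold, and it called 11 unchanged genes. For neurons against hESCs, over 3409 genes, it recovered 10, 32, 47 and 49 of 50 at the same folds, and called 7 unchanged genes. Only those genes were changed in a simulation, as many up as down. It therefore did not test a comparison in which most genes differ, and 2473 of 3439 genes were called between the real neurons and hESCs. The group outside each comparison was simulated from the same baseline. The knockdown simulation thus lacked hESC arrays that differ at most genes, which in the real data share the normalization, detection filter and fit. The simulated folds came out compressed, with a median of 1.85 for a true fold of 2 in the knockdown comparison. The number of arrays limits the precision of every value.

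Alternatives covered the background correction, the scaling between arrays, the offset, the detection filter, the probe used per gene, an added size threshold, the replicate number as a block, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.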

Results

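Transcript levels were compared between undifferentiated HUES9 cells, an established human embryonic stem cell line, and cortical neurons made from them by a default differentiation with BMP4 inhibition. The neurons were harvested at 1.5 months, after infection on day 24 with a lentivirus that carried either a scrambled shRNA (shScramble) or an shRNA against BMI1 (shBMI1). BMI1 is a subunit of Polycomb repressive complex 1, which keeps developmental genes and the CDKN2A locus silent. Each of the 3 groups had 3 arrays. Between 3980 and 4500 of the 9124 probes were detected per array, each read from a median of 20 or 21 beads. Arrays of the same group correlated across the 3439 genes tested with r between 0.9899 and 0.9959, and shBMI1 with shScramble arrays between 0.989 and 0.991. Neurons and hESCs lay further apart, with r between 0.828 and 0.837 for shScramble arrays. Replicate values existed for genes with symbols from A to part way through E, 3439 of which were tested.

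BMI1 itself was lower in shBMI1 than in shScramble neurons by a small margin that did not pass the threshold. Its probe (ILMN_1700915) had a log2 signal of 8.69 ± 0.08 (SD, n = 3) with shScramble and 8.41 ± 0.11 (SD, n = 3) with shBMI1. The difference was -0.28 ± 0.11 (SE), or 1.21-fold, with an adjusted p of 0.155. All 3 shBMI1 arrays, at 8.53, 8.40 and 8.31, lay below the 3 shScramble arrays, at 8.78, 8.64 and 8.66. In hESCs the signal was 6.55 ± 0.19 (SD, n = 3), so that BMI1 was 4.41-fold higher in shScramble neurons than in hESCs (adjusted p = 9.74e-13). BMI1 lay above the hESC level by 1.86 on the log2 scale in the shBMI1 neurons. The array therefore showed a partial difference at most, and the directions below are those between the groups as labelled.

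**Figure D1:**
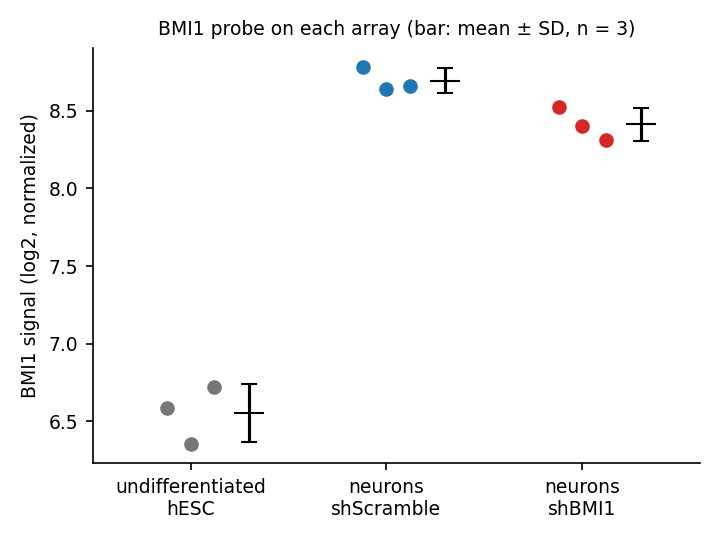
BMI1 signal (log2, normalized) on each of the 9 arrays, as points, with the group mean ± SD (n = 3) beside them. The shBMI1 arrays lie between 8.31 and 8.53, below the shScramble arrays at 8.64 to 8.78 and above the hESC arrays at 6.35 to 6.72.

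The comparison of shBMI1 with shScramble neurons asked which transcripts differ when BMI1 is targeted in human cortical neurons. Synaptic genes, CDKN2B and APP were among 84 genes that rose, and mitotic genes were prominent among 71 that fell. The largest named rise was that of CYP26B1, a retinoic acid-degrading enzyme, from 6.99 ± 0.10 to 7.99 ± 0.02 on the log2 scale (SD, n = 3 each), or 2.0-fold (adjusted p = 2.50e-05). The largest named fall was that of BGN, the matrix proteoglycan biglycan, from 7.15 ± 0.87 to 5.90 ± 0.09 (adjusted p = 0.00847). The changes were small, with a median of 1.39-fold over the 155 called genes; 24 of those that rose and 10 of those that fell reached 1.5-fold. All 155 called genes moved the same way in the authors' group means, which come from the same arrays and are no separate check. For each of these genes the 3 arrays of one group lay entirely above those of the other. Over all genes, 850 of 3439 (24.7%) showed no overlap between the groups, where chance gives 10%.

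Among the other genes with the largest rises were COLEC12, a scavenger receptor (adjusted p = 0.00134), and CRYAB, a small heat shock protein (0.90 ± 0.14 on the log2 scale, SE). DLG4, which encodes the postsynaptic scaffold PSD-95, rose by 0.83 ± 0.12, and CAMK2A, a calcium-dependent kinase of excitatory synapses, by 0.71 ± 0.11. CLIC6, an intracellular chloride channel protein, rose by 0.82 ± 0.11, DKK2, a secreted WNT modulator, by 0.79 ± 0.14, and the lysosomal protease gene CTSL2 by 0.77 ± 0.10. CDKN2B, which encodes the cyclin-dependent kinase inhibitor p15, rose by 0.67 ± 0.10 (adjusted p = 0.00118), as did ACTC1, a cardiac actin, by 0.67 ± 0.11. Among the falls, DLK1, an imprinted Notch ligand homologue, changed by -0.87 ± 0.10 and CMTM7, a membrane protein gene, by -0.87 ± 0.10. B3GAT2, a glucuronyltransferase, changed by -0.72 ± 0.12, the neuropeptide gene CRH by -0.69 ± 0.13, the chemokine CXCL14 by -0.68 ± 0.11 and CLYBL, a mitochondrial enzyme, by -0.63 ± 0.11. The centromere genes CENPH and CENPA and the spindle checkpoint kinase BUB1 changed by -0.62, -0.57 and -0.58. ANKRD52, DCDC5 and CDH23 were, by the 1 probe used for each, detected in shBMI1 neurons and on no shScramble array. They lay at least 1.33-fold, 1.31-fold and 1.30-fold above the detection limit in shScramble neurons. DCDC5 lost its call without each array in turn. CDH23 reversed to -0.0396 without a detection filter, where another probe was used, and to -0.13 without shScramble replicate 2. Its main probe had an SD of 0.05 over the shScramble arrays, so leaving out 1 array cannot reverse that probe. Another probe must have been used there too, and the direction of CDH23 depended on the probe. Of 53 called genes followed through the alternatives for this comparison, between 9 and 25 lost their call when 1 of the 6 arrays was left out. CYP26B1, COLEC12, CRYAB, DLG4, CLIC6, DKK2, CTSL2, CAMK2A, CDKN2B, ACTC1, DLK1, CMTM7, B3GAT2, CXCL14, CLYBL, CENPH, BUB1 and CENPA kept theirs without each array in turn.

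**Figure D2:**
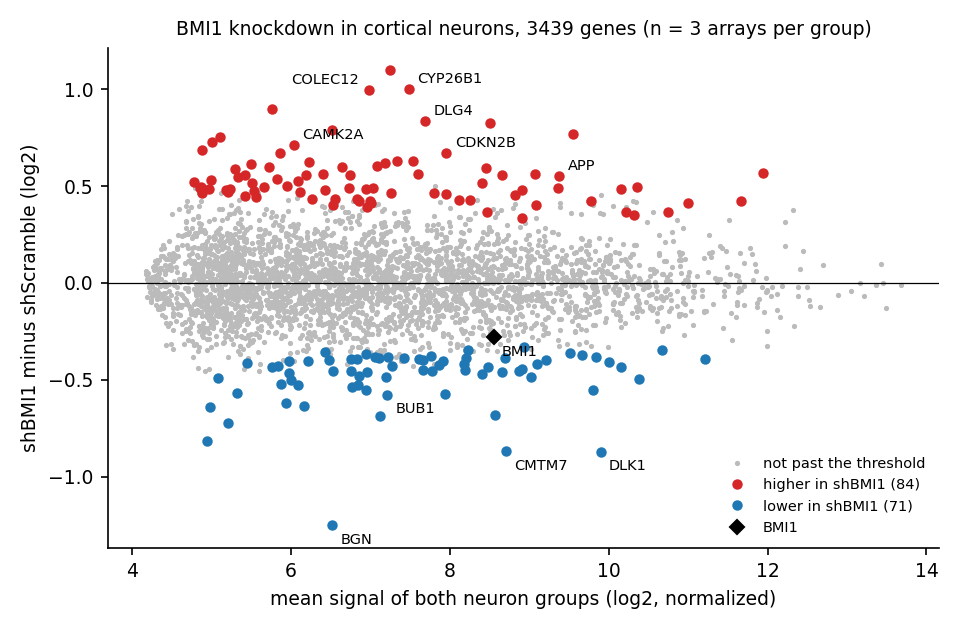
Log2 difference between shBMI1 and shScramble neurons (vertical axis) against the mean log2 signal of both groups (horizontal axis), 1 point per gene for 3439 genes. Red points are the 84 genes that rose and blue points the 71 that fell; BMI1 is the black diamond at -0.28.

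Genes of G2 and mitosis were lower in the shBMI1 neurons as a list. Of 14 measured genes of G2 and mitosis, 5 fell, namely BUB1, CENPA, BIRC5 (-0.55), AURKB (-0.45) and CDC20 (-0.39), and 9 fell when adjusted over the list alone. The highest members were BUB1B at 0.01 and CENPE at -0.13, and 13 of the 14 were negative. The list median of -0.32 lay at percentile 0 of the random lists, and camera gave an adjusted p of 0.0194 with an estimated correlation. Of 6 measured genes of G1 and S phase, 1 fell, the replication helicase factor CDC45L (-0.33), and CDT1 stood at -0.35, CCND1 at -0.12 and CCND2 at 0.09. That list's median was -0.24 (percentile 0.15), with adjusted p = 0.324 with an estimated correlation. Of 5 measured DNA damage response and repair genes, CHEK2 (-0.53) and BRCA1 (-0.48) fell, with ATM at -0.04 and APEX1 at 0.01; the list, at percentile 1.14, did not stand apart. Of 5 measured neural progenitor genes, EMX2 (-0.36) and ASPM (-0.45) fell, with DACH1 at 0.02 (percentile 1.56, median -0.20). Leaving out shScramble replicate 1 ended the calls of AURKB, CDC20, CDC45L, EMX2, ASPM and BRCA1 (adjusted p up to 0.159, for CDC45L), while the G2 and mitosis median stayed at percentile 0 without each array.

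Of 7 measured synaptic genes 3 rose in the shBMI1 neurons, and the list did not pass with an estimated correlation (adjusted p = 0.0583). All 7 were positive, and those that rose were DLG4, CAMK2A and the scaffold DLG2 (0.56 ± 0.11); 4 rose when adjusted over the list alone. CAMK2B stood at 0.41, CPLX2 at 0.09 and CPLX1 at 0.03. The median was 0.41 at percentile 100. The neuronal gene DCX did not pass the threshold, at 0.12 ± 0.13 with an adjusted p of 0.674.

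**Figure D3:**
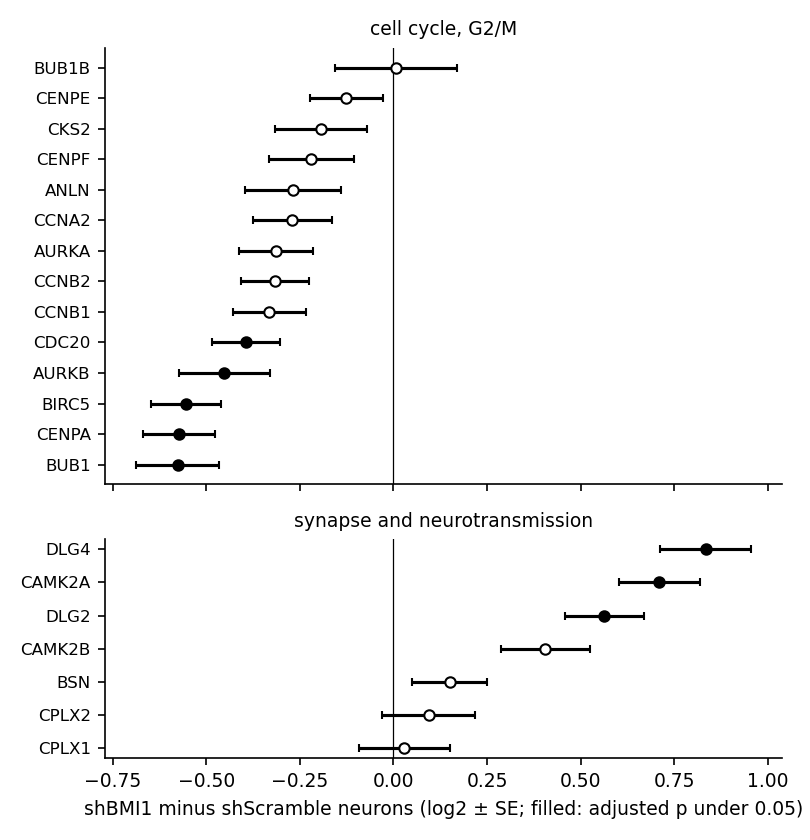
Log2 difference between shBMI1 and shScramble neurons with its SE (horizontal axis, n = 3 arrays per group) for the 14 measured genes of G2 and mitosis (top) and the 7 of the synapse (bottom). Filled points passed the threshold: 5 in the upper panel, all negative, and 3 in the lower panel, all positive.

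Genes linked to Alzheimer disease and to the known targets of BMI1 moved singly. APP, the amyloid precursor protein, rose by 0.55 ± 0.12 (adjusted p = 0.0118) and was the only called member of 9 measured genes of its processing; APH1A stood at 0.27 and APLP1 and APH1B each at -0.04. The APP call was lost without shScramble replicate 1, shBMI1 replicate 1 or shBMI1 replicate 2, with adjusted p of 0.0879, 0.0612 and 0.0677. Of 6 measured genes of tau and its kinases and phosphatases, the CDK5 activator CDK5R1 rose (0.35 ± 0.09), with CDK5R2 at 0.26, CSNK1E at -0.11 and CSNK1D at -0.20; without shScramble replicate 1 the adjusted p of CDK5R1 was 0.171. GSK3B, known here by group means with no error, had intensities of 220 with shScramble and 215 with shBMI1. Of the 6 measured cyclin-dependent kinase inhibitors CDKN2B rose, while CDKN2A stood at 0.27 ± 0.11 (adjusted p = 0.176), CDKN1A at -0.07 and CDKN1C at -0.40. None of 17 measured apoptosis regulators passed the threshold, from BID at -0.18 and CASP6 at -0.15 to BCL2 at 0.20 and BCL2L1 at 0.25. None of the 7 measured subunits of Polycomb repressive complex 1 passed it, with CBX2 at -0.17, BCOR at 0.18 and CBX6 at 0.26 beside BMI1.

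Lists of other cell types held few called genes. Of 4 measured genes of choroid plexus and roof plate, CLIC6 and BMP4 (0.48 ± 0.11) rose, with BMP6 at 0.28 and BMP7 at 0.16; the median was 0.38 at percentile 99.97, with adjusted p = 0.191 with an estimated correlation. Of 3 measured genes of mesoderm and muscle, the actins ACTC1 and ACTA1 (0.49 ± 0.10) rose and EOMES stood at -0.17 (percentile 99.92, adjusted p = 0.241 with an estimated correlation); without a detection filter the list median reversed, from 0.49 to -0.0627. Both actins were nevertheless lower in each neuron group than in hESCs. EOMES is also a member of the list of intermediate progenitors and newborn neurons. None of 3 endoderm and liver genes passed the threshold, with AFP at 0.48, CXCR4 at 0.37 and ALB at 0.08 (percentile 99.27, adjusted p = 0.341 with an estimated correlation). None of 3 astrocyte genes did, with CD44 at -0.37, ALDOC at -0.35 and APOE at 0.31 (percentile 0.5, adjusted p = 0.675 with an estimated correlation); without a detection filter the list median reversed, from -0.35 to 0.0115. Of 11 mesenchyme and fibroblast genes, the smooth muscle actin ACTA2 rose (0.56 ± 0.09) and BGN fell, with CTGF at 0.18 and COL6A2 at -0.44 (percentile 85.8). BGN varied among the shScramble arrays (SD 0.87), and without shBMI1 replicate 2 its call and that of CRH were lost, with adjusted p of 0.0518 and 0.0538.

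The counts depended on the arrays used. Without shBMI1 replicate 2, 30 genes rose and 19 fell; without shBMI1 replicate 1 the numbers were 32 and 22, without shScramble replicate 1 they were 41 and 24, without shBMI1 replicate 3 they were 54 and 35, and without shScramble replicate 3 they were 68 and 28. With cyclic loess scaling 65.1% of the called genes were higher in shBMI1 neurons, against 54.2% in the main setting.

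The comparison of shScramble neurons with hESCs described the change in transcripts between undifferentiated cells and infected neurons. No infection is given for the hESCs. Differentiation, lentiviral infection and time in culture therefore cannot be told apart in it. Genes of newborn neurons and of the synapse were higher in the neurons, and genes of pluripotency and epithelium were lower. With an estimated correlation the adjusted p of each of these lists was 0.0762, and no list of this comparison passed. Of the 3439 genes tested, 1212 rose and 1261 fell, 430 and 381 of them at least 2-fold; with median scaling the balance turned, to 1368 and 1054. DCX, a microtubule protein of migrating neurons, went from 5.39 ± 0.35 to 10.89 ± 0.02 on the log2 scale (SD, n = 3 each), or 45.3-fold (adjusted p = 6.17e-18). The homeobox genes DLX5, DLX1 and EMX2 were not detected in hESCs and were at least 46.6-fold, 39.4-fold and 28.6-fold higher in neurons. The adhesion gene CDH1 went the other way, undetected in neurons and at least 47.8-fold higher in hESCs.

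Among genes detected on both sides, further large rises were those of the Notch ligand DLL1 (5.06 ± 0.11, SE), DLK1 (4.87 ± 0.10), ACTA2 (4.21 ± 0.09), the chemokine CCL2 (18.4-fold), the guidance receptor EPHA4 (3.93 ± 0.12) and the neuronal gene ENC1 (3.83 ± 0.10). The smooth muscle actin ACTG2 rose by 3.68, the ephrin EFNB2 by 3.57 and BCL11B, a factor of deep-layer cortical neurons also known as CTIP2, by 3.56. The largest falls among such genes were those of ACTA1 (-4.95 ± 0.10), the DNA methyltransferase DNMT3B (-4.78 ± 0.12), the epithelial adhesion gene EPCAM (-4.50 ± 0.12), the cadherin CDH3 (-3.98 ± 0.10) and CYBA (-3.94 ± 0.12). COBL, BST2, CYP26A1, DMKN and CGNL1 changed by -3.85, -3.80, -3.67, -3.67 and -3.66. The receptor EPHA1, CYP2S1 and ABHD9 were undetected in neurons and at least 22.4-fold, 21.8-fold and 16.4-fold higher in hESCs.

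All 8 measured genes of intermediate progenitors and newborn neurons rose (median 3.36), among them ELAVL3 (5.56) and, lowest, C7orf16 and ELAVL2, which were at least 1.13-fold and 1.07-fold higher. Of 6 neural progenitor genes 4 rose, with EMX2 and DLL1 highest, ASPM stood at 0.24 and EMX1 fell, at least 1.59-fold higher in hESCs (median 2.77). Of 5 genes of GABAergic neurons 4 rose, led by DLX5 and DLX1, with CALB2 at 0.42 and DLX2 at 0.26 (median 1.81). All 6 synapse genes rose (median 1.42), with BSN at 2.62, CAMK2B at least 4.08-fold, DLG4 at 0.91 and CPLX1 at least 1.64-fold. Of 7 genes of axon growth 6 rose, with DCX and CNTN2 (2.62) highest and DPYSL3 at 0.52, and DCLK1 fell (-0.25; median 1.16). All 6 cyclin-dependent kinase inhibitors rose (median 2.36), among them CDKN2B at least 6.78-fold, CDKN1A by 3.29, CDKN1B by 1.44 and CDKN2A at least 1.6-fold. All 6 pluripotency genes fell (median -3.89), with CDH1 and DNMT3B lowest, DPPA4 at -3.06 and DPPA2 at least 2.59-fold higher in hESCs. All 6 epithelial genes fell (median -3.64), from CDH1 and EPCAM to DSP (-2.21) and ELF3 (-0.54). Of 14 genes of G2 and mitosis 9 fell and 2 rose, with BUB1 at -1.10, BUB1B at -1.03, CENPA at 0.42 and CENPF at 0.70; that list did not stand apart (percentile 3.86). Adjusted p with an estimated correlation was 0.0762 for newborn neurons, synapse, kinase inhibitors, pluripotency and epithelium, 0.0981 for axon growth and GABAergic neurons, and 0.0997 for progenitors.

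Other lists held genes that went both ways. Of 11 genes of mesenchyme and fibroblasts 9 rose, with ACTA2 and COL5A2 (3.11) highest and COL6A2 at 0.16, and BGN fell (-1.17; median 1.26). Of 10 genes of glycolysis and hypoxia 8 fell, with ADM at -3.43 and ALDOC at -2.42, while ENO2 and BNIP3L each rose by 0.94 (median -1.09). Of 6 measured genes near late-onset Alzheimer risk loci 4 fell, EPHA1 and APOE (-3.58) the most, BIN1 rose by 0.59 and CUGBP1 stood at -0.18 (median -1.45). Of 3 astrocyte genes CD44 rose by 2.40 while ALDOC and APOE fell (median -2.42), and of 3 mesoderm and muscle genes EOMES rose at least 7.18-fold while ACTA1 and ACTC1 (-2.35) fell (median -2.35, reversed to 0.0282 without a detection filter). EOMES also belongs to the list of intermediate progenitors and newborn neurons, so its rise is not particular to mesoderm. Adjusted p with an estimated correlation was 0.221 for mesenchyme and for glycolysis, 0.171 for the Alzheimer risk genes, 0.621 for astrocytes and 0.461 for mesoderm and muscle. The 13 lists described for this comparison other than G2 and mitosis stood apart from random lists, and the call of DCLK1 was lost without shScramble replicate 1 or 3 or hESC replicate 2 (adjusted p up to 0.0909). Median scaling put the median of all genes at 0.10, against -0.01 in the main setting, to which smaller differences are relative.

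**Figure D4:**
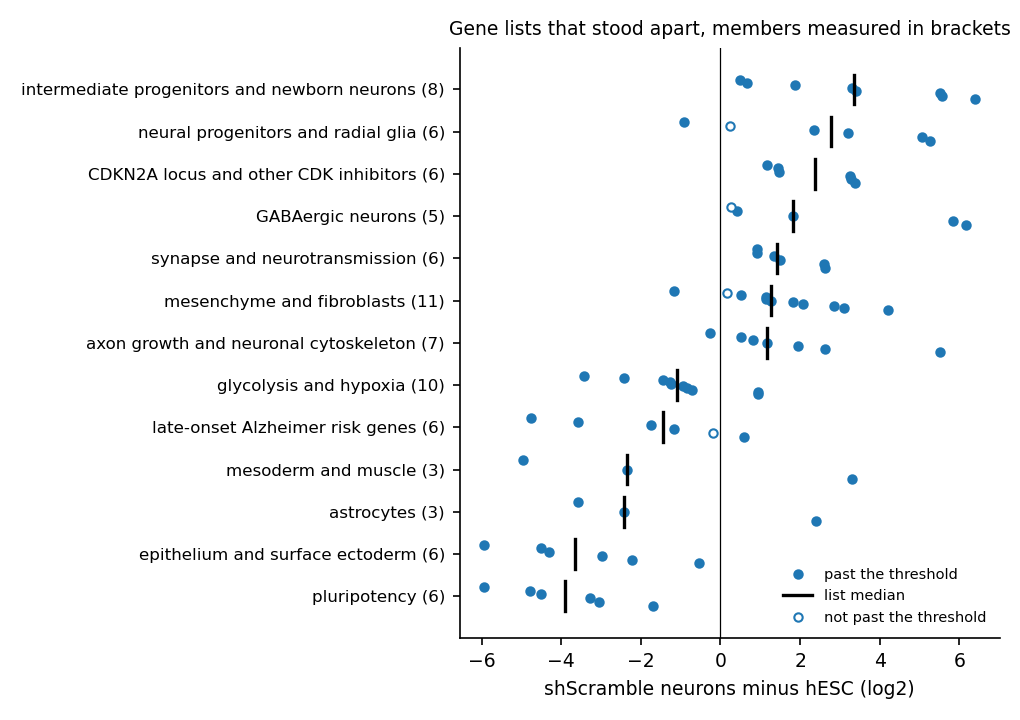
Log2 difference between shScramble neurons and hESCs (horizontal axis) for each measured member of the 13 gene lists that stood apart, with the number of members in brackets; filled points passed the threshold and black bars are list medians. Medians run from -3.89 for pluripotency to 3.36 for intermediate progenitors and newborn neurons; members undetected in 1 group are drawn at their fitted difference, which is not a bound.

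For symbols from part way through E up to HPRT1 the authors' group means added single values without error. The names in these rows were checked by only 5 ubiquitous genes, all above the detection floor. FABP7, a marker of radial glia, had intensities of 5865 with shScramble, 6183 with shBMI1 and 120 in hESCs. The GABA-synthesising enzymes GAD1 and GAD2 stood at 242, 225 and 91.0 and at 171, 179 and 86.2 in the same order, the hESC values of both lying below the detection floor there (103). GAPDH stood at 3732, 3496 and 4830.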

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

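Both tests in this part were chosen after the result was seen.

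In the authors' table of group means, 6846 of the 22626 rows after HPRT1 (30.3%) lay above the detection floor in at least 1 group, a signal in data that no comparison used, and 693 of them differed at least 2-fold between neurons and hESCs. Their names did not match their values. Of 126 genes there that are used by nearly every cell, 46 (36.5%, exact binomial 95% confidence interval 28.1 to 45.6) lay above the floor in hESCs. Low expression of such genes in these cells is argued against by the rows up to HPRT1, where 34 of 34 (100%) lay above it. Of these, 29 had replicate values. Only 5 had group means alone (exact binomial 95% confidence interval 47.8 to 100), so the names of those rows were checked by few genes. Names displaced against values may account for the mismatch: a shift of 3256 rows, found on 50 ribosomal protein rows alone, raised their median intensity from 92.7 to 5695 and put 90.6% of the 64 other ubiquitous genes then in range above the floor, against 35.5% of 76 unshifted. The shift was found from the values, so no gene was renamed by it, and no other biological explanation was tested.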

How the results depend on the processing

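All alternatives were listed before the data were examined except the 2-fold limit and the camera tests. Across them BMI1 stayed below shScramble and outside the threshold: its difference ran from -0.34 to -0.23 without each neuron array in turn, was -0.29 in the authors' table, and had adjusted p between 0.0962 and 0.414. Leaving out each array in turn gave 30 to 75 genes higher and 19 to 75 lower in shBMI1 neurons, 5 to 8 lists apart, and in neurons against hESCs 1162 to 1215 higher, 1192 to 1292 lower and 13 to 14 lists. Fewer arrays were fitted there, and of the calls without shBMI1 replicate 2, 30 and 18 were among the main ones. Without a detection filter 43 genes were higher and 24 lower in shBMI1 neurons and 4 lists stood apart; more genes were then tested. When every detected probe of a gene had to pass in the same direction, 70 genes were higher and 50 lower in shBMI1 neurons. Against hESCs the numbers were 1121 and 1171. Named genes were not followed in that setting, so other probes of a called gene may disagree with the one used. A limit of 1.5-fold left 24 and 10 genes, and 802 and 804 against hESCs. With 2-fold the numbers were 1 and 1, and 430 and 381; with 3-fold 0 and 0, and 205 and 160. By unadjusted p under 0.05, limma found 313 genes higher and 307 lower. With the replicate number as a block 45 genes were lower and 72 higher; equal numbers did not pair the neuron arrays (r = 0.08, 0.08 and -0.07 across genes). CDH23 reversed to -0.0396 at detection p under 0.05 and without a detection filter, where another of its probes was used. It ran from -0.13 without shScramble replicate 2, where the probe must also have differed, to 0.54 without shBMI1 replicate 3. Without a detection filter the median of astrocytes reversed to 0.0115 and that of mesoderm and muscle to -0.0627 and, against hESCs, to 0.0282; the cause was not tested. Of 1476 alternative values of named genes in the knockdown comparison 1327 kept their side of the threshold, 136 lost it, 10 gained it and 3 reversed; against hESCs 1007 of 1015 kept it. List medians kept it in 575 of 609 and 592 of 604 values. These totals include genes and lists that did not pass in the main setting, whose changes of sign were not counted. In the knockdown comparison only 7 of 36 lists stood apart in the main setting. All 16 values that no longer stood apart and the 2 that reversed belong to those 7 lists. Counts were not run on the authors' table, which has 1 value per group. Genes near background have compressed folds, since a signal close to the floor limits what a difference can show.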

Other observations

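The genes named in the first 2 paragraphs were chosen after their values were seen, and so were the test of progenitor markers, that of the BMI1 probe's range, and the bins of signal and shares of called genes along the path from hESC to neuron; the other tests were set before their results were seen.

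Beyond the lists, the single genes below were picked by eye, and no set of such genes was tested. The calcium channel genes CACNA1E (0.56 ± 0.13, SE), CACNA2D3 (0.54 ± 0.15) and CACNA1C (0.47 ± 0.12) rose in the shBMI1 neurons, as did CHGB, a protein of secretory granules (0.63 ± 0.10). The 3 channel calls were lost without shScramble replicate 1 (adjusted p = 0.0882, 0.236 and 0.157). DSCC1, a cohesion gene (-0.53), and the histone chaperone genes CHAF1B (-0.45) and ASF1B (-0.43) fell, and so did CDC2, the mitotic kinase now named CDK1 (-0.46). Without shScramble replicate 1 the adjusted p of CHAF1B, ASF1B and CDC2 lay at 0.158, 0.127 and 0.131. In the authors' group means, the Notch effectors HES5, HES4 and HES1 stood at 1846, 4251 and 248 with shScramble and at 1478, 3052 and 191 with shBMI1, and the glutamate receptor GRIA2 at 181 and 263, all without error.

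Genes known from motile cilia were also seen among the rises: AKAP14 (0.75), C1orf192 (0.73), C11orf88 (0.69), CCNO (0.55), C9orf117 (0.53), DYNLRB2 (0.51) and DNAH1 (0.47). The hypothesis that motile cilia genes rose as a set was then tested on 27 other measured genes of cilia. Their median was 0.0611, at percentile 89.5 of random lists, and 16 of the 27 were positive. None passed the threshold, but the 7 genes left out had been noticed because they were called, so that count decides nothing. The random lists could hold called genes, so they are not a like reference for the 27. The test lay between the bounds set for it, so a general rise of ciliary genes was neither shown nor excluded. These 7 genes may have been picked out of many by chance.

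The lower signals of G2 and mitosis genes in the shBMI1 neurons did not come from the scaling or the background correction, since the median stayed at or below -0.25 under 4 other treatments of the values. Nor did they rest on a single array, since it stayed at or below -0.29 without each neuron array in turn. A smaller share of dividing neural progenitors among the cells stays open: 4 progenitor markers outside the cell cycle had a median of -0.19, at percentile 2.54, which is too few genes to decide. No other biological explanation was tested.

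The small difference in BMI1 could reflect a probe near background, but the probe read 1.86 above hESCs in the shBMI1 neurons, where hESCs were themselves detected on every array. It did not come from a single array either, since the value closest to 0 without each array in turn was -0.23. Since it did not pass the threshold, no difference in BMI1 RNA remains open, as does a modest loss; infection was not measured in the files used here.

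Whether the differences between shBMI1 and shScramble neurons lie along the path from hESC to neuron was left open. Across 3439 genes, which are not independent replicates, the difference correlated with the mean of both neuron groups minus hESC at r = 0.25. In the 9 other splits of the 6 arrays r was at most 0.19 in size, so the prediction set beforehand was met. It does not decide the question, because each of those splits keeps part of the difference between the groups. They therefore give no value for the case of no change. Of the 84 genes that rose, 74 were also higher in neurons than in hESCs (88.1%), and of the 71 that fell 53 were also lower (74.6%), where 49.8% of all genes were higher in neurons. A call required detection in neurons, so genes detected only in hESCs entered the 49.8% but could not be called. The 49.8% is therefore not a matched reference, and for the genes that rose it makes the contrast too large. Within 10 bins of neuron signal, computed after this r was known, r lay between 0.13 and 0.39. With 10 splits no share under 0.05 can be reached.

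For the number of called genes the 10 splits of 6 arrays are too few for a share under 0.05. In the knockdown comparison the real split called 155 genes and the highest of the others 0, so that 1 of the 10 splits gave as many. For shScramble neurons against hESCs the real split called 2473 genes and the highest of the others 0, again 1 of 10. In both comparisons each other split mixes arrays of the real groups, so their difference enters the spread within the mixed groups. The 0 calls there follow largely from that mixing and give no rate of false calls.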
